A study of Mus musculus with 3 samples.

How the data were processed

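Gene expression was measured in total RNA from dorsal skin of 4-day-old female mice of the BALB/cA strain, with 1 biotin-labelled array per sample. Each array had 1 colour. The sources describe 1 wild type sample and 2 uncv null samples, taken from sisters born to uncv heterozygous parents. Groups and replicate numbers were taken from the sample labels. The labels number the uncv null samples as separate samples and the series' design text describes them as mice. P-values of single genes here measure only the spread between those 2 arrays. P-values of gene lists at a preset correlation, and those from permuting list membership, set genes against other genes. They do not measure variation between mice. The extraction reagent is given differently in the labels' protocols and in the series' design text, and this was left open.

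The deposited values are RMA expression values on the log2 scale, per the submitters' processing notes, which name RMA. RMA corrects background, normalizes probe intensities between arrays and summarises the probes of each probe set. The software, its version and the background model are not given in the sources used here, and folds of dim genes depend on the background model. The log2 scale was checked on the values, which ran from 1.96 to 13.1. Because RMA forces the arrays to a common intensity distribution, a shift of all transcripts together could not be seen. No scanner files were used here, so detection calls and signal over background were not used. The number of arrays limits the precision, and there is no counting error to report.

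The table held 45101 probe sets. The 64 control probe sets were kept apart and read only as quality measures. Of the other 45037, 34945 were paired with 1 gene symbol by the platform annotation, 932 with several and 9160 with none. Entrez identifiers of 34741 single-gene probe sets matched the reference gene table, and 0 symbols changed on matching. No genome build is named for the probe sets, so coordinates are not given. Probe sets with a mean log2 value of at least 5 over the 3 arrays were tested, which left 13559 probe sets and 8456 named genes. Each gene was represented by its probe set with the highest mean over the 3 arrays.

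Differences are uncv null minus wild type on the log2 scale. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, Benjamini-Hochberg adjustment over all tested probe sets, threshold 0.05). With 1 wild type array, the spread rests on 1 residual degree of freedom per probe set, moderated over probe sets with 4.75 prior degrees of freedom, and the wild type array is assumed to vary like the uncv null arrays. A gene was also counted by size alone, where both uncv null arrays lay at least 1 log2 unit (2-fold) from wild type in the same direction. The 31 gene lists were fixed with the other choices before the data were examined, unless stated otherwise. Lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation, which here rests on 1 residual degree of freedom. Each list's median was also ranked among 10000 random lists matched on mean expression in 20 bins.

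Named genes followed a rule. It took Rhbdf2, the 12 genes highest and the 12 lowest against wild type among those past both the test and the 2-fold rule, and in each list the 4 members with the largest absolute mean difference. Since 0 genes passed the test, the places were filled from the 2-fold rule, ranked by the smaller of the 2 differences, and clone names were skipped. Further members are named where they passed a test adjusted over their list alone, or where they bear on a list's median, and these were chosen after their values were seen.

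The procedure was tested on simulated data for this comparison. In each of 20 runs over 8456 genes, 200 genes were changed. limma called 6.4% of changes of 1 log2 unit, 83.1% of 2 units, 98.2% of 3 units and 99.6% of 4 units. Of all its calls, 11.2% fell on unchanged genes. The 2-fold rule took in a mean of 68.4 unchanged genes per run. This exceeds the 44 genes past that rule in the data, so their number is no more than simulated unchanged genes gave. The simulated spread came from the fit's prior, and its match to these arrays was not tested. Each change had the same size in both simulated uncv null arrays, and the shares recovered hold for that case alone. A list of 12 genes shifted by 1 unit reached an unadjusted camera p under 0.05 in 20 of 20 runs, and an unshifted list in 0 of 20. Genes were simulated as independent of each other, so these runs do not measure how often camera calls lists of correlated genes. Alternatives were other filters, normalizations, probe set rules, variance models, thresholds and correlations, and leaving out each uncv null array. The wild type array could not be left out.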

Results

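Dorsal skin of 4-day-old uncv null mice was compared with that of a wild type sister. Uncovered (uncv) is a spontaneous mouse mutation with sparse or missing hair, later mapped to Rhbdf2, which encodes the inactive rhomboid protein iRhom2. The comparison asks which transcripts differ in early postnatal skin without normal uncv function. It had 1 wild type and 2 uncv null arrays. Median log2 values over all probe sets were 3.70 in wild type, 3.70 in uncv null 1 and 3.65 in uncv null 2. Over tested probe sets, Pearson's r was 0.972 between wild type and uncv null 1, 0.958 between wild type and uncv null 2, and 0.961 between the uncv null arrays. The wild type array was therefore no farther from uncv null 1 than the uncv null arrays were from each other. The SDs of the log2 differences for these pairs were 0.350, 0.432 and 0.416.

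Rhbdf2 had log2 values of 5.83 in wild type, 6.29 in uncv null 1 and 6.49 in uncv null 2. The mean difference was 0.56 ± 0.27 (limma's moderated SE, 1 against 2 arrays) and did not pass the test (adjusted p = 0.9996). Where its probe set lies relative to the mutation was not examined, so this value does not check the genotype labels. All samples are labelled female. Xist, the X-inactivation transcript, reached 7.62, 7.32 and 7.71 in wild type, uncv null 1 and uncv null 2, while the highest value of any probe set for Kdm5d, Eif2s3y or Uty, genes of the Y chromosome, was 3.65.

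Control probe sets differed between the arrays. The 3 probe sets for 18S ribosomal RNA averaged 3.59 in wild type, 7.93 in uncv null 1 and 4.26 in uncv null 2. The 3' probe set of the Actb control exceeded its 5' probe set by 0.66, 1.23 and 0.79 in the same order. The mean of 18 hybridisation spike-in probe sets lay above wild type by 0.70 in uncv null 1 and 0.43 in uncv null 2. Dim spike-ins differed more. BioB-3, at 4.72 in wild type, lay higher by 0.89 in uncv null 1 and 0.84 in uncv null 2. The bright r2-P1-cre-3, at 12.1 in wild type, differed by 0.30 and -0.06. Whether genes as dim as BioB-3 carry such an offset was not tested.

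By the 2-fold rule, 19 genes were higher and 25 lower in both uncv null arrays than in wild type. The higher genes included secreted defence and acute phase products and keratins of stressed epidermis, and 7 of the 12 lower genes named by rule encode proteins known from muscle. By limma, 0 genes passed the adjusted threshold in either direction (smallest adjusted p = 0.9996), and 245 of 8456 had an unadjusted p under 0.05, of which 134 were higher and 111 lower. With uncv null 2 taken as the lone array instead of wild type, 100 genes lay at least 2-fold from both other arrays on the same side. In simulated data the 2-fold rule took in a mean of 68.4 unchanged genes. That is more than the 44 found here, so their number is no more than simulated unchanged genes gave. How well the simulated spread matched these arrays was not tested. Over all tested genes, 65.2% lay on the same side of wild type in both uncv null arrays, where 66.7% is given by chance because both differences share the wild type array. The values of single genes below are therefore descriptions of these 3 arrays.

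Krt6b and Krt16, keratins of wounded and hyperproliferative epidermis, differed by 3.38 ± 0.78 (10.4-fold) and 2.94 ± 0.70 (7.65-fold). Slpi, a secreted inhibitor of leukocyte proteases, differed by 3.08 ± 0.62. Hp, which encodes haptoglobin, differed by 2.91 ± 0.55. S100a9, a calprotectin subunit, stood 2.41 ± 0.69 above wild type. Tchhl1, a trichohyalin-like protein, was at 1.79 ± 0.39 and the prostaglandin transporter Slco2a1 at 1.43 ± 0.31. Echdc1, a metabolic proofreading enzyme, was at 1.66 ± 0.28. Actn3, the alpha-actinin of fast muscle fibres, was at 1.81 ± 0.44. For 3 further genes the wild type value was close to that array's median of 3.70 and to the 3.65 reached by a Y-linked probe set, so it was not shown to be above background and no size of difference is given. Lrg1, a secreted glycoprotein induced in inflammation, had log2 values of 3.24 in wild type, 6.13 in uncv null 1 and 8.54 in uncv null 2. Serpina3n, an acute phase protease inhibitor, had 3.81, 5.83 and 7.61, and Lrat, which esterifies retinol, had 3.88, 5.33 and 5.96. In all 12 of these genes uncv null 2 lay farther from wild type than uncv null 1.

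Among the lower genes, Tnni1 and Tnnc1, troponins of slow muscle, stood at -2.00 ± 0.32 and -1.82 ± 0.31. Myl4 and Actc1, a myosin light chain and an actin of embryonic and cardiac muscle, were at -2.07 ± 0.52 and -2.08 ± 0.61, and Tnnt2, cardiac troponin T, at -1.64 ± 0.31. Mybph, a myosin-binding protein, was at -1.67 ± 0.39 and Fabp3, the fatty acid-binding protein of heart and muscle, at -1.55 ± 0.27. Fmod, which encodes the collagen-binding proteoglycan fibromodulin, had values of 7.17 in wild type, 5.63 in uncv null 1 and 3.71 in uncv null 2, the last at the level of that array's median. Wfdc18 was at -2.07 ± 0.55, Coch, an extracellular matrix protein, at -1.55 ± 0.28, and Mbp, myelin basic protein, at -1.57 ± 0.33. With the mean of a gene's probe sets, Myl4 was at -1.19, Fabp3 at -0.75, Mbp at -1.005 and Rian at -0.80. Rian, an imprinted noncoding RNA, was at -1.39 ± 0.30 by its representative probe set and was the exception in which uncv null 1 lay farther from wild type. Of the 44 genes past the 2-fold rule, 4 had another tested probe set. In 7 of these 8 other probe sets the difference had the same sign.

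**Figure D1:**
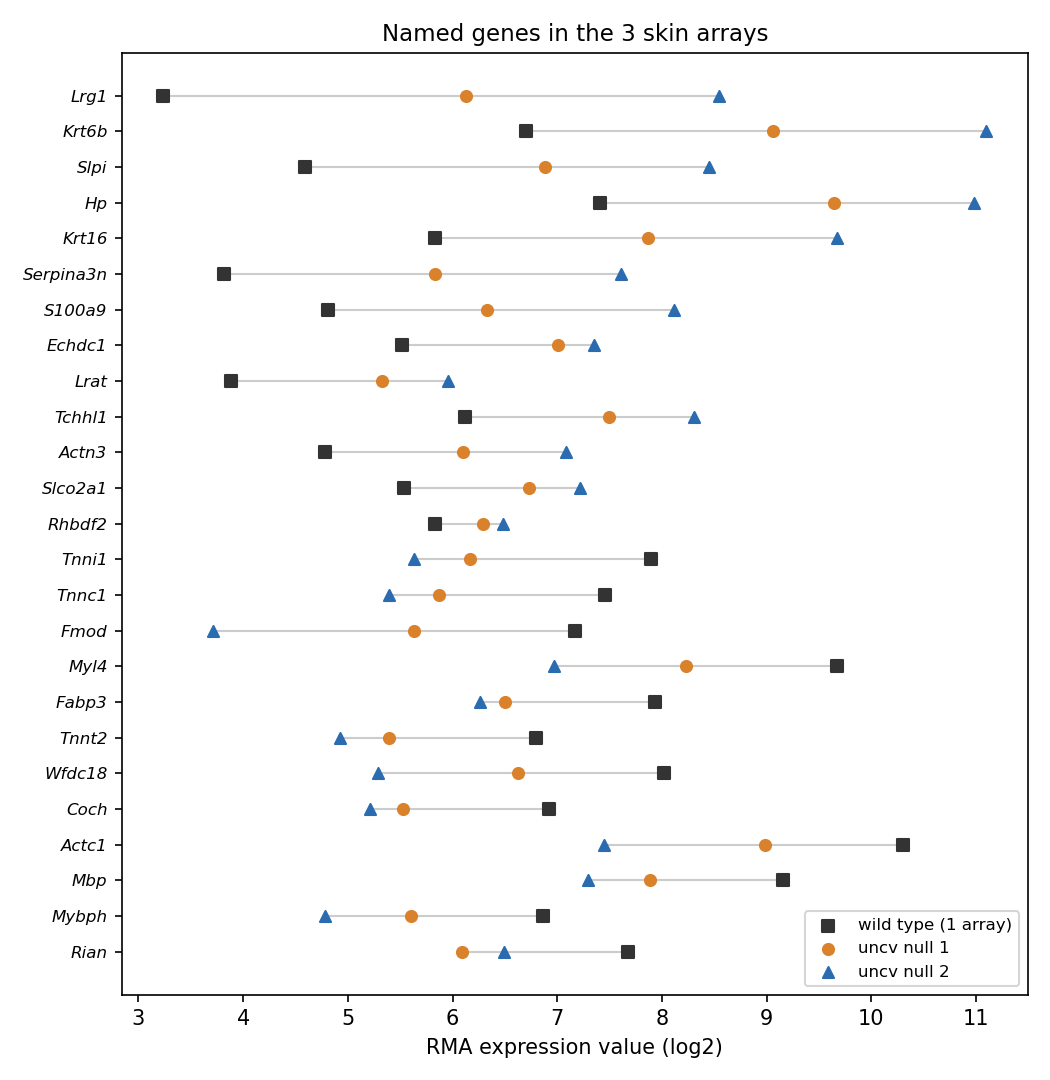
Log2 RMA expression values (x axis) of the genes named by rule (y axis) in the wild type array (squares), uncv null 1 (circles) and uncv null 2 (triangles), each point 1 array; grey lines span the 3 values. Krt6b runs from 6.70 in wild type over 9.06 to 11.1, and in all genes shown except Rian the uncv null 1 value lies between the other two.

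Gene lists were tested as sets. Of 26 lists with enough measured genes, camera called 17 at the preset correlation, 13 higher and 4 lower in uncv null skin. With an estimated correlation it called 0 of them (smallest adjusted p = 0.63). That test rests on 1 residual degree of freedom, where even a large shift can hardly pass, so its 0 calls decide nothing. The preset calls are left without a check on correlation between genes. With uncv null 2 as the lone array, 19 lists were called. Of all 8456 tested genes, 38.8% lay above wild type in both uncv null arrays and 26.4% below, and the counts of list members on each side stand beside these shares. In what follows, a list that rose or fell passed the preset test, each median is given for uncv null 1 and then uncv null 2, and all measured members failed the adjustment over all tested genes. Values of single members are means over both uncv null arrays, and for 58 of the 128 genes named by rule leaving out 1 array moved the value by over 1.5 times or turned its sign. The mean spike-in offset noted above ran in the same direction in both uncv null arrays. For the dim spike-in BioB-3 it was at least as large as many of the member values below.

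Stress keratins and alarmins formed the list with the largest rise. The list for hyperproliferative and stressed epidermis rose (12 genes, median 1.00, camera adjusted p = 1.6e-12, or adjusted p = 0.63 with an estimated correlation), and its medians were 0.75 and 1.32. All 12 measured members were higher in both uncv null arrays, 4 of them past the 2-fold rule, namely Krt6b, Krt16, S100a9 and S100a8. The list names 26 genes, and with no filter, where dimmer members enter, its median was 0.67. Krt6b and Krt16 passed when adjusted over the list alone (limma adjusted p = 0.038 for each). S100a8, the partner of S100a9, was at 1.97 ± 0.64. The 4 measured small proline-rich proteins, which are cornified envelope precursors, were all higher in both arrays, with a median of 0.77 (medians 0.69 and 0.87). With no filter, where dimmer members enter, the median was 0.36 (adjusted p = 7.7e-04). Sprr1b was at 1.24, Sprr2d at 0.87, Sprr2h at 0.67 and Sprr1a at 0.53. Krt6a, at 1.13, is close in sequence to Krt6b, and an array may not separate such paralogs fully. Structural epidermal genes moved less. The basal epidermis list rose (13 genes, median 0.37, medians 0.20 and 0.45, adjusted p = 6.5e-04, or adjusted p = 0.63 with an estimated correlation), led by the hemidesmosomal and matrix-binding genes Itgb4 at 1.07, Itga3 at 0.89, Dst at 0.83 and Lama3 at 0.45. With the mean of probe sets Dst was much smaller, as given below. The list for the granular layer and cornified envelope also rose (31 genes, median 0.18, medians 0.15 and 0.17, adjusted p = 0.025, or adjusted p = 0.63 with an estimated correlation), with 18 members higher and 1 lower in both arrays. Its leading members were Klk7 at 0.67, Nipal4 at 0.61, Evpl at 0.50 and Ivl at 0.46. This call was also lost at a preset correlation of 0.05 (adjusted p = 0.12). The spinous list was not called (14 genes, median 0.11, medians 0.16 and 0.19, adjusted p = 0.12), though it was called higher with no filter (adjusted p = 0.020), the mean of probe sets (0.028) and an intensity trend (0.027); Jup was at 0.50, Pkp1 at 0.42, Notch1 at 0.35 and Dsp at 0.33.

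Genes of the hair shaft did not pass in either direction. Of 11 measured hair shaft keratins, 1 was higher and 0 lower in both arrays, and the median was -0.05 (adjusted p = 0.43). The arrays disagreed in sign, at -0.29 in uncv null 1 and 0.18 in uncv null 2. Krt32 was at 0.43. Krt81, Krt83 and Krt33b differed in sign between the arrays, at -0.71, -0.65 and -0.41 in uncv null 1 and 0.011, 0.081 and 0.025 in uncv null 2. The 34 keratin-associated proteins, the matrix proteins of the shaft, had a median of -0.03 (medians -0.36 and 0.37, adjusted p = 0.22) and of 0.03 at a minimum mean of 7, with 6 members higher and 6 lower in both arrays. Krtap19-1 was at -1.21 and Krtap5-1 at -1.13. Krtap6-3 was at -0.10 in uncv null 1 and 2.64 in uncv null 2, and Krtap6-2 at 0.34 and 1.84; members of this family share sequence, so single members are uncertain. Regulators of the hair matrix and shaft had a median of 0.0059 over 12 genes (medians -0.09 and 0.22, adjusted p = 0.86), which was -0.02 with no filter. Hephl1 was at 0.59, Wnt5a at -0.57, Wnt10a at 0.43 and Dlx3 at 0.36. The inner root sheath list rose (14 genes, median 0.24, medians 0.13 and 0.37, adjusted p = 0.0024, or adjusted p = 0.63 with an estimated correlation), and 12 of its members were higher in both arrays. Its leading members were Padi1 at 0.92, an enzyme also known from the epidermis, Gata3 at 0.62, Prr9 at 0.44 and Krt26 at 0.39. The list for the outer root sheath, companion layer and bulge rose (16 genes, median 0.32, adjusted p = 0.023, or adjusted p = 0.63 with an estimated correlation), with medians of 0.09 and 0.54 in the 2 arrays. Its call was also lost at a preset correlation of 0.05 (adjusted p = 0.075). It was led by Krt6b, Krt16 and Krt6a, which the stress list also holds, and by Krt75 at 0.66, the companion layer keratin. Of its 16 members 9 were higher in both arrays, and the 3 lower in both, Cd34 at -0.62, Nfatc1 at -0.42 and Krt15 at -0.42, are known from the bulge, as are Sox9 at 0.41, Lhx2 at 0.32 and Lgr5, which was at -0.22 in uncv null 1 and 0.74 in uncv null 2. Genes known from inherited hair loss rose as a list (15 genes, median 0.27, medians 0.23 and 0.32, adjusted p = 0.0022, or adjusted p = 0.63 with an estimated correlation). Vdr was at 0.82, Hr at 0.63 and Liph at 0.60, beside Rhbdf2.

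The signalling lists included the pathway in which iRhom2 acts, the shedding of ligands of the epidermal growth factor receptor by the protease ADAM17. This list rose (12 genes, median 0.37, medians 0.30 and 0.48, adjusted p = 2.3e-04, or adjusted p = 0.63 with an estimated correlation), with 11 members higher in both arrays. Its call was also lost at a minimum mean of 7 (adjusted p = 0.055), and with the mean of probe sets its median was 0.19. Hbegf, Egf, Tnf and Map3k8 were below the filter and Areg had no single-gene probe set, so these were not measured. Transcript values do not measure shedding. The basal epidermis list also had a median of 0.37, so a rise particular to this pathway was not shown. The ligand Epgn was at 0.88, Rhbdf2 at 0.56, Adam17 at 0.49 and the receptor Erbb2 at 0.48, but with the mean of probe sets Adam17 was at -0.16. The hedgehog list fell over both arrays together (10 genes, median -0.22, adjusted p = 0.018, or adjusted p = 0.68 with an estimated correlation), but its median was 0.0041 in uncv null 1 and -0.38 in uncv null 2. Its call was also lost at a minimum mean of 7 (adjusted p = 0.061) and with the mean of probe sets (median -0.12, adjusted p = 0.23). Cdon was at 0.08 in uncv null 1 and -0.83 in uncv null 2, the pathway target Gli1 at -0.33, the receptor Ptch1 at -0.33 and Boc at -0.28. Dermal papilla genes were not called (10 genes, median -0.17, medians -0.08 and -0.23, adjusted p = 0.076), though with no filter they were called lower (median -0.26, adjusted p = 4.9e-05), and the median was -0.45 at a minimum mean of 7 and -0.09 with the mean of probe sets; Trps1 was at -0.77, Prom1 at 0.69, Vcan at -0.51 and Sox18 at -0.39. Cell cycle genes were not called either (30 genes, median 0.06, medians -0.05 and 0.06, adjusted p = 0.43), and here the median was above 0 while the mean of -0.015 and the test pointed lower, as did the median of -0.04 with the mean of probe sets. Cenpe was at 0.74, Ccne2 at -0.67, Bub1b at 0.47 and Rrm1 at -0.44. Immediate early and stress genes rose (16 genes, median 0.37, medians 0.16 and 0.47, adjusted p = 0.0013, or adjusted p = 0.63 with an estimated correlation). Nr4a1 was at 0.76, Egr1 at 0.73, Zfp36 at 0.57 and Fos at 0.56.

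Lipid-related lists rose together. White adipocyte genes rose (12 genes, median 0.70, medians 0.50 and 0.96, adjusted p = 1.5e-08, or adjusted p = 0.63 with an estimated correlation), with all 12 higher in both arrays. The adipokine Retn was at 0.75 in uncv null 1 and 2.53 in uncv null 2, and the lipid droplet protein Cidec at 0.49 and 1.60. By their means over both arrays, the lipase Pnpla2 was at 0.87 and the lipase Lipe at 0.81. With the mean of probe sets Pnpla2 was much smaller, as given below. The sebaceous gland and skin lipid list rose (12 genes, median 0.41, medians 0.24 and 0.71, adjusted p = 8.1e-05, or adjusted p = 0.63 with an estimated correlation), with Degs2 at 0.83, Far2 at 0.77, Scd3 at 0.73 and Fa2h at 0.61. Cholesterol synthesis genes rose (15 genes, median 0.28, medians 0.18 and 0.48, adjusted p = 0.0020, or adjusted p = 0.65 with an estimated correlation), with Hsd17b7 at 0.66, Msmo1 at 0.48, Nsdhl at 0.40 and Dhcr7 at 0.39. The cholesterol call was also lost with the mean of probe sets (median 0.17, adjusted p = 0.0505). The 4 measured brown adipocyte genes had a median of -0.25 (medians -0.35 and -0.17), but of -0.02 with no filter and 0.38 at a minimum mean of 7, so the list has no settled direction. Besides Fabp3, which passed when adjusted over the list alone (limma adjusted p = 0.0057), Cox8b was at -0.78. Cidea was at -0.24 in uncv null 1 and 1.19 in uncv null 2, and Elovl3 at -0.18 and 0.76.

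Markers of other tissues in the sample also differed. Skeletal muscle genes fell (25 genes, median -0.72, medians -0.59 and -0.85, adjusted p = 1.8e-17, or adjusted p = 0.63 with an estimated correlation), with 21 lower and 2 higher in both arrays. Myh3, the embryonic myosin heavy chain, was at -0.87 in uncv null 1 and -3.19 in uncv null 2. Tnni1, Tnnc1, Tnnt1 at -1.09 and Tnnt3 at -1.02 passed as lower when adjusted over the list alone, and Actn3 as higher (limma adjusted p from 0.015 for Tnni1 to 0.045 for Tnnt3). Schwann cell and nerve genes fell (6 genes, median -0.53, medians -0.32 and -0.74, adjusted p = 1.9e-04, or adjusted p = 0.63 with an estimated correlation). Mbp and Gap43, at -1.34, passed when adjusted over the list alone (limma adjusted p = 0.022 and 0.048), while Pmp22 was at -0.66 and Egr2 at 0.41. Dermal fibroblast and matrix genes fell (17 genes, median -0.26, medians -0.08 and -0.44, adjusted p = 3.2e-05, or adjusted p = 0.63 with an estimated correlation), with 15 lower in both arrays, among them Lox at -0.87, Mfap5 at -0.72 and Fbln1 at -0.51, while Eln was at -0.05 in uncv null 1 and -1.36 in uncv null 2. The macrophage list rose (12 genes, median 0.29, medians 0.12 and 0.43, adjusted p = 0.011, or adjusted p = 0.63 with an estimated correlation), with Lyz2 at 0.65, Cd163 at 0.54, Mrc1 at 0.51 and C1qb at 0.44. The list for T cells and Langerhans cells rose (6 genes, median 0.42, medians 0.22 and 0.59, adjusted p = 0.0065, or adjusted p = 0.63 with an estimated correlation). It was led by Ptprc at 0.76, H2-Ab1 at 0.59, H2-Aa at 0.46 and Cd74 at 0.38, which mark leukocytes and antigen-presenting cells. The T cell genes Cd3e, Cd3g, Cd3d and Cd247 and the Langerhans cell gene Cd207 fell below the filter. Lck and Trdc had no single-gene probe set, so the rise does not speak for T cells. The last call was lost with no filter (median 0.18, adjusted p = 0.070).

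The remaining lists gave no call or were too short to test. Endothelial genes had a median of -0.0044 over 10 genes (adjusted p = 0.051) but of -0.13 in each uncv null array alone, and were called lower with no filter (adjusted p = 0.032), cyclic loess (0.049) and the mean of probe sets (0.023); Tek was at -0.77, Emcn at -0.71, Egfl7 at -0.48 and Sox7 at 0.20. Melanocyte genes had a median of -0.03 over 9 genes with a test pointing higher (adjusted p = 0.55), and the medians were -0.19 and 0.42. At a minimum mean of 7 their median was 0.09, and with the mean of probe sets it was 0.08. Mitf was at 0.57, Kit at 0.50, Ednrb at 0.36, and Sox10 was at 0.03 in uncv null 1 and -0.54 in uncv null 2. Mast cell genes had a median of -0.07 over 8 genes, with a mean of 0.035 (medians 0.06 and -0.17, adjusted p = 0.86); Hdc was at 1.00, Tpsb2 at -0.78, Kit at 0.50 and Mcpt4 at -0.45. Of 14 listed red blood cell genes 2 were measured, Alas2 at -0.92 and Hbb-b2 at -0.83, which passed as lower when adjusted over these 2 alone (limma adjusted p = 0.035 for each). With no filter the red blood cell list had a median of -0.02 and was not called (adjusted p = 0.27). The neutrophil list kept only S100a8 and S100a9, which keratinocytes also make and which passed when adjusted over these 2 alone (limma adjusted p = 0.023 for each). In the stress list of 12 measured genes the same 2 did not pass when adjusted over that list. S100a9, at 4.81 in wild type, met the filter through its uncv null values. An adjustment over 2 genes is slight, here and for the red blood cell genes, and none was made over the lists. With no filter the neutrophil list was called higher, with a median of 0.24 (adjusted p = 0.010). Of 20 listed interferon response genes 2 were measured, Ifih1 at 0.73 and Rsad2 at -0.02, and with no filter the interferon response list had a median of 0.10 and was not called (adjusted p = 0.15).

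**Figure D2:**
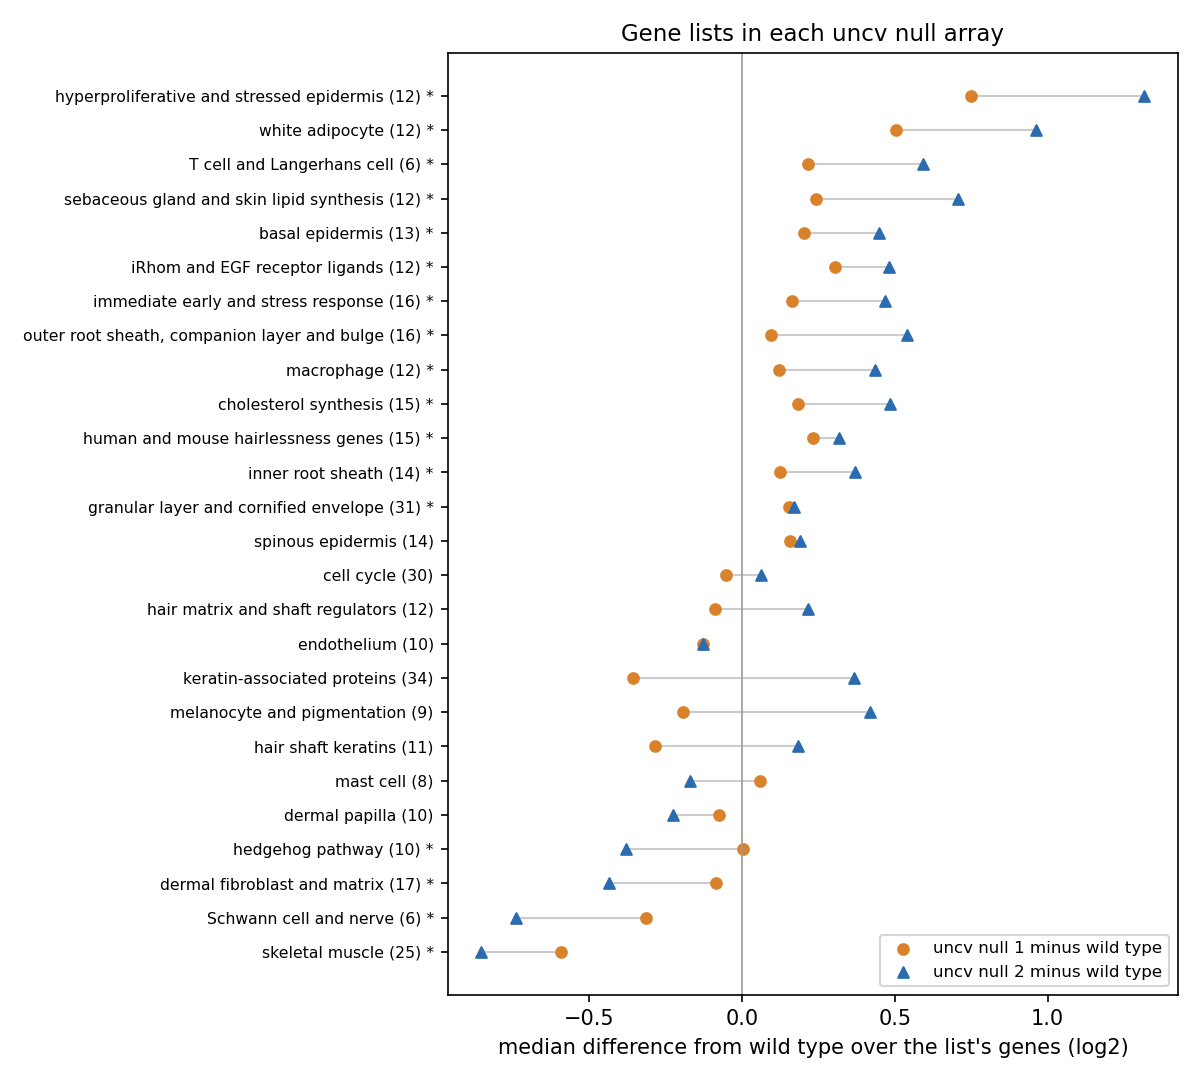
Median log2 difference from the wild type array (x axis) over the measured genes of each fixed list (y axis, number of genes in brackets) in uncv null 1 (circles) and uncv null 2 (triangles); an asterisk marks lists called by camera at the preset correlation. The stress list reached 0.75 and 1.32, skeletal muscle -0.59 and -0.85, and keratin-associated proteins lay on opposite sides of 0 at -0.36 and 0.37.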

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

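The 18S ribosomal RNA control probe sets, which belong to no comparison above, gave a signal in 1 array. Their mean in uncv null 1 lay 4.34 log2 units (20.3-fold) above wild type, against 0.67 in uncv null 2. This was singled out because it is a signal outside the main measurement and above its level in the wild type array. In the same array the 3' probe set of the Gapdh control exceeded the 5' one by 0.02, against -0.29 in wild type and -0.27 in uncv null 2.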

How the results depend on the processing

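The count of 0 genes by limma held with no filter, a minimum mean of 7, quantile, median or cyclic loess normalization, the mean of a gene's probe sets, an intensity trend, robust eBayes and a threshold of 0.01. It became 61 genes (25 higher, 36 lower) with one spread for all probe sets, and 245 at an unadjusted p under 0.05. The 44 genes of the 2-fold rule (19 higher, 25 lower) became 11 (6 and 5) at a minimum mean of 7, where fewer genes were tested, 240 (126 and 114) at 1.5-fold and 7 (6 and 1) at 3-fold. Leaving out 1 uncv null array gave 80 to 294 genes (38 to 130 higher, 42 to 164 lower); the lower value is uncv null 1 alone and the higher uncv null 2 alone. Of the 44 genes, 41 remained under quantile normalization and 30 with the mean of probe sets. Called lists numbered 12 to 21 under the filters, normalizations, probe set rule and trend, 15 at a correlation of 0.05 and 0 with the estimated one, which leaves 1 degree of freedom. Over all these except the estimated correlation, 10 list calls were lost, 3 of them because fewer than 5 genes were left, and 9 gained: spinous epidermis and endothelium 3 each, and dermal papilla, small proline-rich proteins and neutrophils with no filter, the last 2 being too short to test otherwise. The other losses, for which the cause was not tested, were hedgehog with the mean of probe sets and at a minimum mean of 7 (adjusted p over alternatives 0.0033 to 0.23), granular layer (0.0067 to 0.12) and outer root sheath (0.0032 to 0.075) at a correlation of 0.05, iRhom and EGF receptor ligands at a minimum mean of 7 (2.7e-05 to 0.055), cholesterol with the mean of probe sets (1.1e-04 to 0.0505), and T cells and Langerhans cells with no filter (0.0043 to 0.070). The hedgehog median changed sign, from -0.38 in uncv null 2 alone to 0.0041 in uncv null 1 alone. Of 128 genes named by rule, 58 moved by over 1.5 times or changed sign when 1 array was left out. Sign changed for 4 without uncv null 1 (Krt81, Krt83, Krt33b, Rsad2) and for 5 without uncv null 2 (Krtap6-3, Cdon, Sox10, Cidea, Elovl3), and for Rsad2 with arrays centred on their median. With the mean of probe sets 18 moved as far, among them Dst (0.24) and Pnpla2 (0.33), and Adam17 changed sign (-0.16). The 25 named genes past the 2-fold rule, chosen for one sign in both arrays, kept it. Leaving out an array leaves 1 against 1, so those values have no test, and the wild type array could not be left out. No paired analysis was possible because the wild type has 1 array and carries no replicate number.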

Other observations

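The tests in this part on the epidermal share, on RNA quality, on the muscle share, on the dermal share and on the count of 2-fold genes, the lists for muscle isoforms and acute phase genes, and the hair lists with another lone array, were chosen after the results they bear on had been seen. A set of 13 measured acute phase and secreted defence genes had a median of 0.63, and 10 were higher in both uncv null arrays. Lrg1, Hp, Slpi, Serpina3n and the protease inhibitor Timp1, at 1.66, had been seen when the list was written, so its median is not independent of them. Among the others, the oncostatin M receptor Osmr stood at 0.63, the transcription factor Stat3 at 0.60 and its feedback inhibitor Socs3 at 0.55. The metallothioneins Mt1 and Mt2 were at -0.14 and -0.39. Probe sets that recognise several Sprr2a genes, and so name none of them, stood 2.23 and 1.94 above wild type in uncv null 1 and 2.71 and 3.04 in uncv null 2.

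Muscle isoforms were sorted by developmental stage. The 13 measured embryonic, neonatal and cardiac isoforms had a median of -1.64 (-1.07 in uncv null 1 and -1.88 in uncv null 2), with 12 lower in both arrays. The 17 adult fast isoforms had a median of -0.55 (-0.52 and -0.71), with 13 lower and 3 higher. The first list holds Tnni1 and Tnnc1, which slow muscle also uses, and slow Tnnt1 is in neither list. Myog, which drives myoblast differentiation, was at -1.36, while the fast-fibre genes Mybpc2 and Actn3 were at 1.46 and 1.81. The 12 measured imprinted and fetal growth genes, listed before their values were looked at, had a median of -0.33 with 9 lower and 0 higher in both arrays. Their medians were -0.25 in uncv null 1 and -0.56 in uncv null 2. Cdkn1c, an imprinted cell cycle inhibitor, was at -0.59 in uncv null 1 and -1.68 in uncv null 2. In the same order, Dlk1 was at -0.25 and -1.10, Ndn at -0.29 and -1.03, and Plagl1 at -0.28 and -1.02.

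The higher stress keratins and S100 genes may reflect several processes. A larger epidermal share would raise structural epidermal genes as much as the stress list's 1.00, or 0.67 with no filter. The 58 structural members had a median of 0.18 with an upper quartile of 0.33, short of that size. Some were bright, such as Krt10 at 12.8 in wild type, and whether differences are compressed there was not tested. Dimmer members went both ways. Itgb4 and Itga3, at 5.40 and 5.27 in wild type, stood at 1.07 and 0.89. Tgm5 and Lce3b, at 5.57 and 5.45, stood at 0.02 and -0.22. The quartile argues against a larger share as the whole cause only if bright members were not compressed. The RNA quality of uncv null 1 is argued against by the stress list's medians, 1.32 in uncv null 2 and 0.75 in uncv null 1. The 18S signal of uncv null 2 was near that of wild type. A technical difference shared by both uncv null arrays, such as the spike-in offset, was not tested. Neutrophils as a source of S100a8 and S100a9 remain open. The median of 0.20 over 10 other neutrophil genes decides nothing, since several lay near background, with Prtn3, Mmp8, Mmp9 and Cxcr2 under 3.65 in every array. Camp had 4.26 in wild type, 4.84 in uncv null 1 and 5.38 in uncv null 2, while Ltf had 5.93, 4.70 and 3.44, the last also under 3.65. An effect of the genotype remains open and untested beyond these arrays.

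The lower embryonic muscle isoforms have as candidate explanations less muscle in the sample or a later stage of the uncv null skin. Less muscle stays open: the medians of the isoform lists differed by -1.09, but 7 embryonic and 2 adult members were 2-fold genes, and values of several members had been seen when the lists were written, so this difference decides nothing. A later stage predicted lower imprinted and fetal growth genes. Their median of -0.33 met that prediction over both arrays together, at percentile 0.01 of random lists. The median was -0.25 in uncv null 1, which alone fell short of the size set beforehand, and -0.56 in uncv null 2. The percentile does not single these genes out, since the dermal fibroblast and skeletal muscle lists stood at percentile 0 and white adipocyte at 100. The median of -0.33 differed by -0.067 from that of the dermal fibroblast list (permutation over 29 genes, 2-sided p = 0.51), so a smaller dermal share stays open as its source. All samples are labelled with the same age, and a difference in maturity between the wild type sister and the others could not be separated from genotype with 1 wild type array.

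Uncv null 2 stood apart from the other arrays more than the wild type did, with 100 genes at least 2-fold from both others, against 44 for wild type. A wider intensity distribution of its array is argued against, since quantile normalization gave 105 genes against 45. Taking each array in turn as the lone one gives 3 choices, too few for a share under 0.05. For the 2-fold genes, 2 of the 3 choices reached the 44 of the real one, and the highest other was 100. For called lists, 2 of the 3 reached the 17 of the real one, and the highest other was 19.

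With uncv null 1 as the lone array, 3 lists were called at the preset correlation: hair shaft keratins (camera adjusted p = 2.6e-06), keratin-associated proteins (2.5e-21) and melanocyte genes (0.015). The medians of their differences, the other arrays minus uncv null 1, were 0.38, 0.59 and 0.38. With uncv null 2 as the lone array the same lists were called the other way (camera adjusted p = 0.0049, 7.8e-11 and 0.0042), with medians of -0.37, -0.55 and -0.60. With an estimated correlation none was called, but that test rests on 1 residual degree of freedom and decides nothing. None of the 3 was called with wild type as the lone array, and by their medians the wild type lay between the uncv null arrays.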
